A study of Arabidopsis thaliana with 24 samples.

How the data were processed

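RNA of roots and of rosette leaves of Arabidopsis plants given nano-titania, nano-ceria, KCl or millipore water was hybridised to 24 Affymetrix ATH1 arrays, with 15 ug of RNA in the labelling step per the labels. The labels call the replicates biological and do not tie a leaf and a root array of the same number to the same plants. The deposited values are log2 values, 1 per probe set and array, which the authors obtained with RMA, that is background correction, quantile normalization and median-polish summary. The version of that software and whether all arrays were normalized together are not stated. Values ran from 2.13 to 14.50, with none missing, and array medians lay between 4.96 and 5.15. The deposited table held 0 control probe sets and 22746 others, and all were tested. Of these, 14016 were in the probe annotation, and 13513 of them pointed to 1 gene and 503 to several. The 13355 genes so named include 11933 known by a locus code alone, and 8730 probe sets without a listed gene were tested but are not named. Positions come from the RefSeq table of the TAIR10.1 assembly. No genome sequence was used.

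Linear models were fitted with limma 3.58.1 in R 4.3.3 to the 12 arrays of a tissue, with a mean for each of the 4 groups, and to all 24 arrays for comparisons between tissues. Moderated limma tests were two-sided. Benjamini-Hochberg adjustment ran over all 22746 probe sets within each of the 11 comparisons, with a threshold of 0.05. The comparisons were, in each tissue, TiO2 against KCl, CeO2 against water, the TiO2 effect against the CeO2 effect and KCl against water, and then the TiO2 effect and the CeO2 effect in roots against leaves, and roots against leaves over the control plants. Between-tissue differences of an effect and differences between particles are tests of the difference itself. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.

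Genes named in the text followed a rule written before the data were examined. For TiO2 or CeO2 against its control these are the 10 largest rises and the 10 largest falls among probe sets of 1 gene that passed and whose treated and control arrays did not overlap, filled up to 5 in each direction by the smallest unadjusted p and then given as not passing. For the other comparisons they are the 5 largest in each direction, filled up to 3. Up to 4 passing members of each gene list are added, or the members with the smallest p as values. Members whose adjustment over the list alone passed are also named, and these were chosen after their values were seen. That adjustment ran within each list and not across the lists. Lists held as few as 1 named gene, for which the p value stays unadjusted. The rule also asked for ACT2, UBQ10, PP2AA3, RBCS1A, LHCB3 and TIP2;3, for which no named probe set was found here, so PEX4, AT4G34270 and AT2G28390 stand for the reference genes.

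The gene lists comprised 38 written before the data were examined and 24 written after the annotation had been read, from gene symbols, without regard to their values. The 24 were added because 87 of the 649 genes of the first lists had a named probe set, and only these are called measured. They cover 6 of 19 heat shock, 5 of 31 abscisic acid and cold and 4 of 18 carbon starvation genes. They also cover 3 of 13 chlorophyll synthesis and 2 of 17 aliphatic glucosinolate genes. The first kind include photosystem and Calvin cycle, chlorophyll synthesis, antioxidant enzymes, flavonoid and anthocyanin, abscisic acid and cold, heat shock, carbon starvation, aliphatic glucosinolate and the reference genes. The added kind include the plastid- and mitochondrion-encoded genes, nuclear photosynthesis genes, ATG8 (with ATG3), tubulins, core histones, branched-chain amino acid breakdown and cytosolic ribosome lists. For a gene with several probe sets the one with the highest mean was used. Lists of at least 5 genes, 6 of the first kind and 24 of the added kind, were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 30 lists within a comparison. The same was done with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance in 1 direction. Of 104 list calls, 5 held with an estimated correlation and 22 with fry. With an estimated correlation these were 4 for roots against leaves in control plants and 1 for KCl against water in roots. By fry, whether called by camera or not, 21 lists passed for roots against leaves in control plants. It was 2 for TiO2 in leaves, 3 for TiO2 in roots and 1 each for the particle difference and KCl against water in roots. No list passed by fry in the other comparisons, which include CeO2 against water in each tissue. All 104 kept the sign of their median when arrays were quantile-normalized again or centred on their medians. Centring moved the median of all probe sets by more than 0.1 in 4 comparisons: TiO2 against CeO2 effect in leaves (-0.11) and roots (0.13), KCl against water in roots (-0.12) and the TiO2 effect in roots against leaves (0.19).

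Pairing by replicate number was checked by correlating the deviations from the group mean of arrays with the same number. All 3 correlations were positive for KCl and water roots (0.374, 0.341 and 0.176) and for leaves and roots given CeO2 (0.3, 0.332 and 0.258). They were not for the other pairs of groups checked, which were not all possible pairs. No block entered the fits. With the replicate number as a block, the 27 probe sets called for KCl against water in roots became 0.

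The fits were tested on simulated data with the spread of these arrays. Of 200 genes given a log2 change of 1, 2 or 3, the test recovered 95, 152 and 174 in leaves with TiO2 and 53, 124 and 176 in roots with TiO2, with 5.6% and 7.6% of the calls false. With CeO2 it recovered 76, 152 and 180 in leaves and 52, 122 and 170 in roots. With nothing planted it made 0 calls. Noise was drawn independently for each probe set, without the variation that probe sets of an array share. The shares of false calls and the 0 calls therefore need not hold for these arrays.

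Alternatives fixed before the data were examined were a replicate block, fits to the compared groups alone or to all 24 arrays, filters at the 25th percentile and the median of the mean signal, quantile normalization, median-centred arrays, an intensity trend with robust priors, array weights, a threshold of 0.1, an unadjusted p under 0.05 with a log2 change of at least 1, and leaving out each array. After the arrays had been seen, the lower quartile of each array as a covariate and the omission of the 6 arrays with a lower quartile above 3.7 were added.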

Results

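Transcript levels were measured on Affymetrix ATH1 arrays in roots and in rosette leaves of Arabidopsis thaliana Col-0 plants aged 29 days. Plants had received nano-titania (TiO2) or nano-ceria (CeO2) at 500 mg/L on days 0, 4 and 17. The titania suspensions were prepared in KCl and the ceria suspensions in millipore water, so that the titania plants received the salt of their KCl control. The KCl solution is 0.1 mM in the sample descriptions and 0.1 M in the treatment protocol. The 24 arrays formed 8 groups of 3, with 4 groups in each tissue. Each array gave a log2 signal for 22746 probe sets, with array medians from 4.96 to 5.15. Pearson correlations between arrays of the same group ran from 0.873 to 0.99. On 6 arrays the lower quartile of the log2 signal was above 3.7, so that their values spanned a narrower range. These were replicates 1 and 3 of the KCl roots (3.90 and 3.74), replicate 2 of the TiO2 roots (3.78), replicate 1 of the water roots (3.73), replicate 2 of the KCl leaves (3.75) and replicate 2 of the CeO2 leaves (3.79). Differences are in log2 units with the standard error of the difference, group levels are means with the SD of 3 arrays, and adjusted p values come from limma. Genes that passed over all probe sets separated the groups compared on every array in each particle or salt comparison. The number of arrays limits the precision.

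Roots and leaves of control plants differed in photosynthesis and root-specific genes. All 29 nuclear photosynthesis genes were lower in roots, and 28 of them fell in the test over all probe sets. PSAN, a subunit of photosystem I, was at -7.49 ± 0.48 (adjusted p = 9.13e-10). PIFI, a factor of chlororespiration, was at -7.25 ± 0.23 (adjusted p = 1.88e-13). The list's median was -4.98 (adjusted p = 7.64e-31; adjusted p = 0.0145 with an estimated correlation). All 5 photosystem and Calvin cycle genes fell, with a median of -5.85 (adjusted p = 0.0341 with an estimated correlation). Of 26 photosystem and cytochrome genes encoded in the plastid, 24 fell, with a median of -2.98 (adjusted p = 0.0341 with an estimated correlation). PYK10, the beta-glucosidase of root endoplasmic reticulum bodies, rose by 6.89 ± 0.63 in roots (adjusted p = 8.85e-08). The lectins JAL33, JAL22 and JAL34 were higher in roots by 6.65, 5.29 and 4.79. Of the 7 genes of the jacalin lectin and PYK10 list, 6 rose (adjusted p = 5e-06; adjusted p = 0.116 with an estimated correlation). Among 55 class III peroxidases, 22 rose in roots and 2 fell, and among 128 cytosolic ribosomal genes, 55 rose and 2 fell. The reference genes PEX4, AT4G34270 and AT2G28390 differed by 0.03, 0.47 and 0.47, and none passed. In all, 4370 probe sets were higher in roots and 3503 were lower.

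The comparison of TiO2 with KCl roots asks what nano-titania does to root transcripts. Heat shock and cold-response genes were higher in roots given TiO2. AT5G48570 (ROF2, a heat-induced FK506-binding protein; TAIR10.1 chromosome 5, 19690461 to 19693845) rose by 4.03 ± 0.49 (adjusted p = 0.0131), from 3.62 ± 0.66 to 7.65 ± 0.67. AT1G53540, a small heat shock protein, rose by 4.22 ± 0.68 (adjusted p = 0.036), from 3.73 ± 0.18 to 7.95 ± 1.71. Both were near the KCl level in the roots given water (3.56 ± 0.57 and 3.71 ± 0.37) and in those given CeO2 (3.40 ± 0.68 and 3.84 ± 0.58). All 6 heat shock genes with a named probe set, of 19 on the list, were higher with TiO2. Of these, 4 rose adjusted over the list alone, with AT2G29500 at 3.14 and HSA32 at 1.25 beside the pair above. The list's median was 2.22 (adjusted p = 2.88e-07; adjusted p = 0.189 with an estimated correlation).

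**Figure D1:**
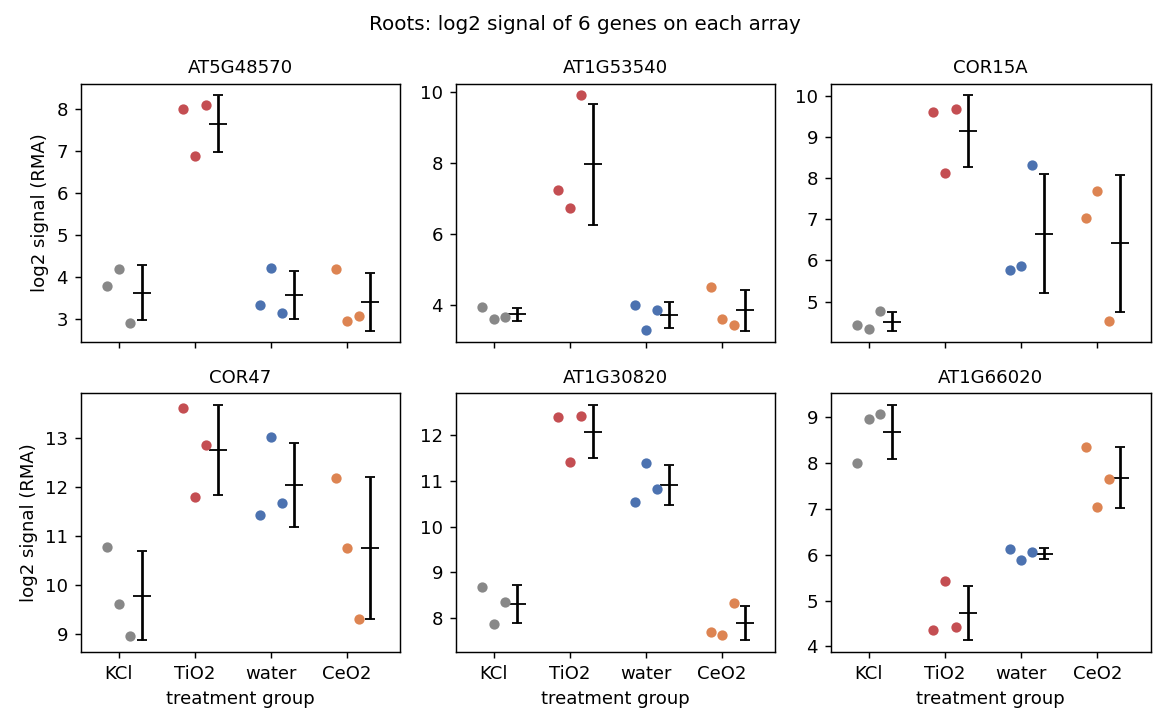
Log2 signal of 6 genes in roots on each of the 3 arrays of the 4 treatment groups, with the group mean and SD as a black bar beside the points; the vertical axes differ between panels and do not start at 0. AT5G48570 averages 7.65 in TiO2 roots and 3.40 to 3.62 in the other groups, while COR15A is lowest in KCl roots at 4.52.

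All 5 measured genes of the abscisic acid and cold list rose with TiO2 in roots, adjusted over the list alone, and 1 of them, COR15B, over all probe sets (1.57 ± 0.22, adjusted p = 0.0199). COR15A, a chloroplast-targeted protein made in the cold, was at 4.63, the dehydrins LTI30 and COR47 at 3.67 and 2.97, and LEA4-5 at 2.68. The median was 2.97 (adjusted p = 7.92e-09; adjusted p = 0.12 with an estimated correlation). COR15A averaged 4.52 ± 0.22 in KCl roots, 9.14 ± 0.87 in TiO2 roots, 6.65 ± 1.44 in water roots and 6.42 ± 1.67 in CeO2 roots. In the same order COR47 averaged 9.78 ± 0.91, 12.75 ± 0.92, 12.04 ± 0.85 and 10.75 ± 1.45. LTI30 averaged 9.37 ± 0.85, 13.04 ± 1.33, 12.25 ± 0.32 and 11.73 ± 1.425. KCl roots held the lowest mean of each gene of this list. All 4 measured carbon starvation genes rose adjusted over the list alone: PPDK, which makes phosphoenolpyruvate, at 3.38, the methylcrotonyl-CoA carboxylase subunits MCCA and MCCB at 2.72 and 1.44, and IVD of leucine breakdown at 1.92. KCl roots held the lowest group mean of each, such as 5.89 ± 0.12 for MCCA against 8.61 ± 0.67 with TiO2, 6.90 ± 0.28 with water and 7.05 ± 1.28 with CeO2. The 8 genes of branched-chain amino acid breakdown had a median of 1.58, and 2 of them, MCCA and ETFQO, rose adjusted over the list alone (list adjusted p = 2.54e-05; adjusted p = 0.423 with an estimated correlation). Both measured genes of aliphatic glucosinolate synthesis fell adjusted over the list alone, BCAT4 at -3.21 and AT2G31790 at -1.30.

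Genes of the organelles and of chromatin lay lower in TiO2 than in KCl roots, and KCl roots had the highest mean of the 4 root groups in the lists that follow. The median signal of the plastid-encoded ribosome and polymerase genes averaged 7.77 ± 0.36 in KCl, 6.76 ± 0.74 in TiO2, 5.64 ± 0.69 in water and 6.57 ± 1.42 in CeO2 roots (SD over arrays). It was 7.71 ± 0.42, 6.25 ± 1.09, 6.22 ± 0.45 and 6.52 ± 0.55 in the same order for mitochondrion-encoded genes, and 6.81 ± 0.24, 6.04 ± 0.12, 5.49 ± 0.50 and 5.48 ± 0.44 for core histones. Tubulins were lowest in KCl roots, at 7.63 ± 1.18 against 8.86 ± 0.67, 8.85 ± 0.73 and 8.69 ± 0.25. All 19 plastid-encoded ribosome and polymerase genes were lower, with a median of -0.94, and 3 fell adjusted over the list alone (adjusted p = 0.000144; adjusted p = 0.473 with an estimated correlation). For 26 plastid-encoded photosystem and cytochrome genes the median was -0.86 and 0 passed adjusted over the list alone (limma; adjusted p = 2.09e-05; adjusted p = 0.473 with an estimated correlation). The 16 mitochondrion-encoded genes had a median of -1.24, and 3 fell adjusted over the list alone, among them nad9 at -1.81 (adjusted p = 0.000144; adjusted p = 0.473 with an estimated correlation). Of 8 core histone genes, HTB1, AT2G28720 and AT2G37470 fell adjusted over the list alone, at -1.55, -1.49 and -1.37 (median -0.56, adjusted p = 0.0206; adjusted p = 0.288 with an estimated correlation). Without replicate 2 of the KCl roots or replicate 2 of the TiO2 roots the histone list did not pass, and the highest adjusted p was 0.393. The 7 tubulin genes were all higher, with a median of 0.94, and TUA1 rose adjusted over the list alone at 2.12 (list adjusted p = 0.00148; adjusted p = 0.423 with an estimated correlation). KCl roots 1 and 3 and TiO2 root 2 were among the 6 arrays with a narrow range.

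Other genes differed strongly between TiO2 and KCl roots. AT1G30820, which encodes a CTP synthase (TAIR10.1 chromosome 1, 10944908 to 10949482), rose by 3.76 ± 0.36 (adjusted p = 0.0079), from 8.31 ± 0.41 to 12.07 ± 0.58. It stood at 10.91 ± 0.43 in water roots and 7.89 ± 0.38 in CeO2 roots. AT3G17130 rose by 3.77 ± 0.64, from 4.64 ± 0.98 to 8.41 ± 0.57, with 8.01 ± 0.64 in water roots and 5.13 ± 1.15 in CeO2 roots. AT4G34950 rose by 2.72, and GSA1 of chlorophyll synthesis rose by 1.16 ± 0.16 (adjusted p = 0.0215). AT5G51680, AT3G07565, AT1G73480, AT1G16840 and AT2G47890 rose by 3.01, 2.71, 2.52, 2.15 and 2.06. AT1G66020 (TAIR10.1 chromosome 1, 24577544 to 24580185) fell by 3.94 ± 0.41 (adjusted p = 0.00862), from 8.67 ± 0.59 to 4.73 ± 0.60, with 6.02 ± 0.12 in water roots and 7.68 ± 0.66 in CeO2 roots. AT1G31050 was at -3.65, BAT1 (AT4G31910), an acyltransferase of brassinosteroid metabolism, at -3.39, and AT1G48750 at -2.87. The methionine sulfoxide reductase MSRB5 was at -2.50, and LHW (LONESOME HIGHWAY), a regulator of root vascular tissue, at -2.39. AT4G20230, AT5G01090, AT1G23410 and AT1G33440 fell by 2.95, 2.19, 2.12 and 2.11. GSTU23, a glutathione S-transferase, fell by 1.77 ± 0.30 (adjusted p = 0.0431). In AT1G30820, AT4G34950, GSA1, AT1G16840, AT1G31050, LHW and AT1G23410 KCl roots also lay apart from water roots, on the same side as from TiO2 roots. The values are given below with the controls. For AT3G17130 and AT1G66020 the KCl means above also lie on the same side of the water means as of the TiO2 means. In these and in AT1G30820 the CeO2 mean was nearer to the KCl mean than to the TiO2 mean.

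Over all probe sets, 46 rose and 33 fell in TiO2 roots, of which 36 had a named gene. With arrays centred on their medians the split was 71 up and 32 down, and when quantile-normalized again it was 59 up and 59 down. With the replicate number as a block 34 passed and 18 of the 23 passing genes named here lost their call, and in a fit to the compared groups alone 3 passed and all 23 lost it. For 54 of the 79 the KCl mean lay farther than the TiO2 mean from the average of the water and CeO2 roots. For 25 the TiO2 mean lay farther. Among probe sets with an unadjusted p under 0.05 the KCl mean lay farther in 74%. Where water and CeO2 roots lie apart, this measure does not tell which group moved. In AT1G30820 TiO2 roots (12.07) stood nearest to water roots (10.91) and KCl roots (8.31) nearest to CeO2 roots (7.89). An unadjusted p under 0.05 was met by 2839 probe sets, against 1137 by chance, and 15.3% of all probe sets separated the groups, against 10% by chance. The count fell to 4 without TiO2 replicate 3, to 7 without TiO2 replicate 1 and to 15 without KCl replicate 3, and rose to 456 without TiO2 replicate 2. It was 0 without the 6 narrow arrays, which leaves 1 KCl array that is assumed to vary like the other groups.

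In leaves, fewer genes passed after TiO2, and KCl leaves differed from the other 3 groups in most of those named. AT1G29670, a GDSL-type lipase (TAIR10.1 chromosome 1, 10375599 to 10377871), rose by 3.92 ± 0.46 (adjusted p = 0.0386), from 6.67 ± 0.15 with KCl to 10.59 ± 0.52 with TiO2, and stood at 9.94 ± 0.68 with water and 9.23 ± 0.88 with CeO2. AT3G52870 rose by 2.58 ± 0.31 (adjusted p = 0.0397), from 4.76 to 7.34, with 7.18 in water leaves and 7.08 in CeO2 leaves. AT4G26950 (TAIR10.1 chromosome 4, 13533391 to 13534498) fell by 3.45 ± 0.33 (adjusted p = 0.0247), from 6.97 ± 0.46 to 3.52 ± 0.04, with 3.89 ± 0.50 in water leaves and 3.87 ± 0.54 in CeO2 leaves. AT5G11930 fell by 3.03 ± 0.33 (adjusted p = 0.0258), from 7.53 ± 0.14 to 4.50 ± 0.29, with 4.22 ± 0.59 and 5.71 ± 0.53 in water and CeO2 leaves. In all 5 probe sets that passed, the KCl mean lay farther than the TiO2 mean from the average of the water and CeO2 leaves, but among the 3523 with an unadjusted p under 0.05 it did so in 53.6%. Differences that did not pass included AT3G10720 at 3.27, AT1G04430 at 2.39, AT4G27720 at 1.43, ROXY2 at -2.18 and AT3G62650 at -1.33 (adjusted p from 0.0571 to 0.0851).

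**Figure D2:**
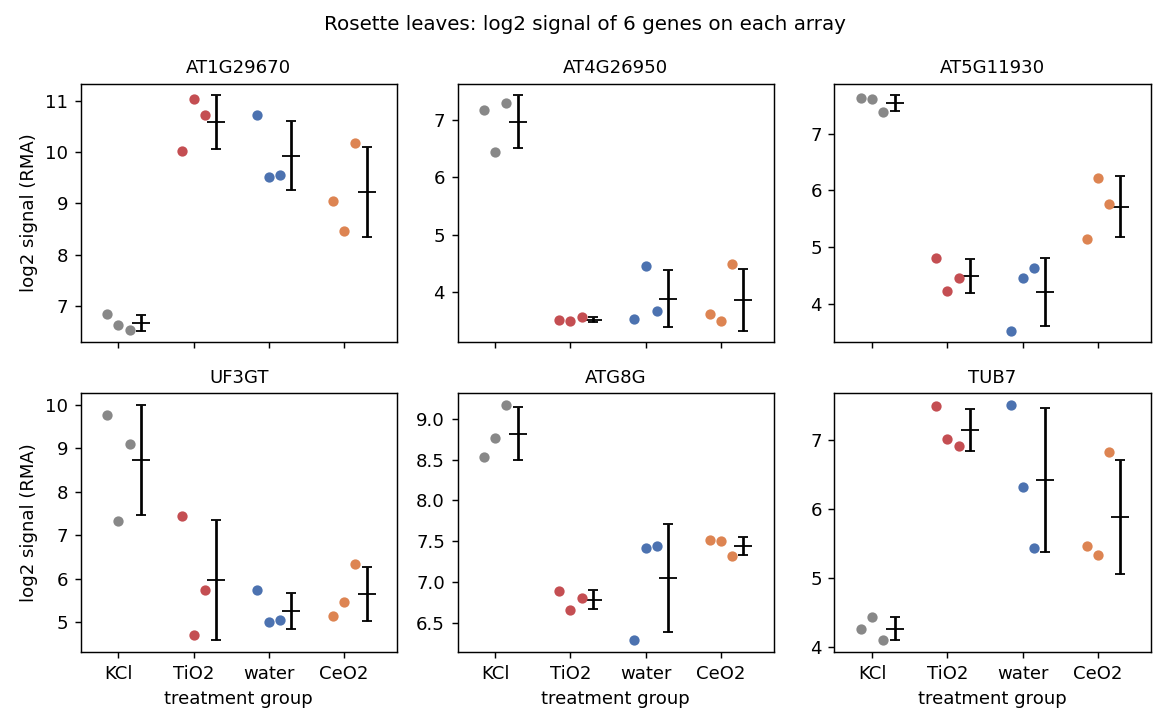
Log2 signal of 6 genes in rosette leaves on each of the 3 arrays of the 4 treatment groups, with the group mean and SD as a black bar beside the points; the vertical axes differ between panels and do not start at 0. AT1G29670 averages 6.67 in KCl leaves and 9.23 to 10.59 in the other groups.

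Nuclear photosynthesis and tubulin genes lay higher and autophagy, flavonoid and mitochondrial genes lower in TiO2 than in KCl leaves. KCl leaves also lay apart from water leaves in these lists, on the same side as from TiO2 leaves. The list medians for KCl against water were -0.37, -1.41, 0.95, 3.21 and 0.83 in that order. The nuclear photosynthesis list did not pass there in 3 of 6 fits with an array left out. The KCl arrays enter both comparisons. All 7 tubulin genes rose adjusted over the list alone, with TUB7 at 2.87, TUB5 at 2.17 and TUB6 at 2.09 (median 1.65, adjusted p = 2.67e-07; adjusted p = 0.512 with an estimated correlation). Of 29 nuclear photosynthesis genes 27 were higher, with a median of 0.90, but 0 passed adjusted over the list alone (limma; adjusted p = 1.05e-08; adjusted p = 0.512 with an estimated correlation). The plastid-encoded photosystem and NDH lists did not follow. For the photosystem and cytochrome genes the median was -0.31, with 19 of 26 lower. For the NDH genes it was -0.06, with 5 of 10 lower, and neither list passed (camera adjusted p = 0.487 and 0.945). The plastid-encoded ribosome and polymerase list did not pass against KCl either. Its TiO2 effect was more positive than its CeO2 effect (median 0.785), a call kept with each array left out, while CeO2 against water gave -0.544. Among the 5 photosystem and Calvin cycle genes SBPASE, sedoheptulose-bisphosphatase, rose adjusted over the list alone at 2.11 ± 0.62 (list adjusted p = 0.00135; adjusted p = 0.512 with an estimated correlation). All 3 measured chlorophyll synthesis genes rose adjusted over the list alone, PORB at 2.27, CHLM at 1.49 and GSA1 at 0.97. Among 10 genes of the ATG8 autophagy system, 8 fell adjusted over the list alone, such as ATG8B at -2.17, ATG8G at -2.04 and APG8A at -1.64 (median -1.49, adjusted p = 3.05e-06; adjusted p = 0.512 with an estimated correlation). ATG8G averaged 8.82 ± 0.32 in KCl leaves against 6.78 ± 0.12, 7.04 ± 0.66 and 7.45 ± 0.11 in TiO2, water and CeO2 leaves. The anthocyanin enzymes UF3GT, AT4G14090 and AT5MAT fell adjusted over the list alone, at -2.77, -2.61 and -1.83, and all 5 flavonoid genes were lower (median -2.61, adjusted p = 0.00647; adjusted p = 0.512 with an estimated correlation). Of 16 mitochondrion-encoded genes, 9 fell adjusted over the list alone, with nad6 at -2.10 and nad1 at -2.03 (median -1.19, adjusted p = 0.0027; adjusted p = 0.792 with an estimated correlation). The 5 antioxidant enzyme genes were all higher with a median of 0.79 and 0 passed adjusted over the list alone (adjusted p = 0.0122; adjusted p = 0.512 with an estimated correlation). That list did not pass without replicate 2 of the KCl or of the TiO2 leaves (highest adjusted p = 0.055). The reference gene PEX4 fell adjusted over the list alone, at -1.07, and AT4G34270 and AT2G28390 differed by 0.42 and 0.61 without passing.

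In TiO2 leaves 3 probe sets rose and 2 fell, and with median-centred arrays 1 rose and 2 fell. An unadjusted p under 0.05 was met by 3523, against 1137 by chance, and 25.2% separated the groups, against 10% by chance. The count became 135 without KCl replicate 1, 17 without KCl replicate 2 or TiO2 replicate 1, and 0 without KCl replicate 3 or TiO2 replicates 2 or 3. KCl leaf 2 was among the narrow arrays; without the 6 narrow arrays 8 passed, which shared 1 probe set with the reported 5, and 3 of the 4 named genes lost their call.

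The comparison of CeO2 with water asks the same of nano-ceria. In roots, AT1G30820, the CTP synthase gene, fell by 3.02 ± 0.36 with CeO2 (adjusted p = 0.0392), from 10.91 ± 0.43 in water roots to 7.89 ± 0.38. It was the only named gene among the 2 probe sets that rose and the 2 that fell, and its call was lost in all 6 fits with an array left out, with the replicate number as a block or the compared groups alone (0 probe sets passed in both) and with either other scaling. Differences that did not pass were AT1G28100 at 2.49, AT5G04080 at 2.19, AT5G58200 at 2.52, AT4G00040 at 2.31 and AARE at 1.19 above water, and AT4G34950 at -3.26, AT1G06830 at -3.80, AT1G49650 at -1.93 and AT5G64640 at -1.47. Adjusted over the list alone, RCA (rubisco activase) rose at 1.80 and the glutathione S-transferase GSTU20 fell at -2.71. BCAT4 of methionine chain elongation, on the glucosinolate list, fell at -2.39, and AT3G45700, on the potassium and chloride transport list, fell at -1.92. The serine carboxypeptidase scpl31 rose at 2.43 and the peroxidase AT1G44970 fell at -1.24, adjusted over the list alone. All 10 genes of the ATG8 list, which also holds ATG3, were higher, with a median of 0.42 (adjusted p = 0.0181; adjusted p = 0.797 with an estimated correlation), and all 15 GH9 endoglucanases were lower, with a median of -0.21 (adjusted p = 0.0118; adjusted p = 0.674 with an estimated correlation). Plastid ribosome and polymerase genes had a median of 0.85 (adjusted p = 0.00964; adjusted p = 0.797 with an estimated correlation), and in these 3 lists 0 genes passed adjusted over the list alone. Each of the 3 lists failed without at least 1 array: the ATG8 list without CeO2 replicate 3 (adjusted p = 0.828), endoglucanases without the same array (0.0613) and the plastid genes without CeO2 replicate 1 (0.529), and without water replicate 2 each failed too. By limma 1523 probe sets met an unadjusted p under 0.05, against 1137 by chance, and 13% separated the groups, against 10% by chance. The count of 4 became 0 without any of the 3 water arrays or CeO2 replicate 3, and 1 without CeO2 replicate 1. Water root 1 was among the 6 narrow arrays, without which 0 passed. With median-centred arrays 0 rose and 1 fell.

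In leaves, CeO2 gave 0 probe sets by limma, with 503 at an unadjusted p under 0.05 against 1137 by chance, and 5.2% separating the groups against 10% by chance. The settings tried gave 0 or 1, save for 146 at an unadjusted p under 0.05 with a change of at least 1. Small shifts ran along lists. Of 29 nuclear photosynthesis genes 28 were lower, with a median of -0.37 and PRK, phosphoribulokinase, at -1.05 (adjusted p = 6.23e-08; adjusted p = 0.738 with an estimated correlation). The 5 photosystem and Calvin cycle genes were all lower, with a median of -0.66 (adjusted p = 0.00023; adjusted p = 0.487 with an estimated correlation). The plastid-encoded ribosome and polymerase genes had a median of -0.54 (adjusted p = 2.01e-08; adjusted p = 0.223 with an estimated correlation) and the NDH genes of the plastid a median of -0.44 (adjusted p = 0.0011; adjusted p = 0.223 with an estimated correlation). Of 128 cytosolic ribosomal genes 106 were higher, with a median of 0.24 (adjusted p = 3.47e-07; adjusted p = 0.806 with an estimated correlation), a call lost without CeO2 replicate 3 (adjusted p = 0.313). No member of these lists passed adjusted over the list alone. Differences with the smallest unadjusted p in each direction, none of which passed, were AT2G17850 at 1.68, AT1G19530 at 1.63, AT5G11930 at 1.497, AT1G68650 at 0.63 and AT5G20160 at 0.63, and SIS at -1.82, AT3G10720 at -1.78, ycf4 at -0.94, AT3G01560 at -0.82 and AT4G13550 at -0.68.

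The effects of the particles, each against its own control, differed in roots. AT1G30820 differed most clearly, by 6.78 ± 0.50 (adjusted p = 0.00171), having risen with TiO2 and fallen with CeO2. A difference of effects equals TiO2 minus CeO2 with KCl minus water taken off, so a gap between the controls enters it. AT1G30820 averaged 8.31 in KCl roots and 10.91 in water roots. AT5G55450 differed by 8.01 ± 1.43 (adjusted p = 0.041). It averaged 3.92 ± 0.39 in KCl roots, 8.77 ± 1.23 with TiO2, 9.10 ± 1.34 with water and 5.94 ± 2.06 with CeO2. For this gene KCl and water roots lay farther apart than TiO2 and CeO2 roots. AT3G17130, AT4G34950 and AT5G22580 had a more positive TiO2 effect by 6.65, 5.98 and 5.39. AT5G10580, AT1G66020, AT1G49310, AT4G34600 and AT1G48750 had a more negative one, at -6.13, -5.60, -4.85, -4.46 and -4.13. Members of lists that passed were AT5G48570 at 4.19 ± 0.69, GSA1 at 1.63, COR15B at 1.74 and AT1G44970 at 2.11. For the abscisic acid and cold list the median was 4.19, and 4 of 5 passed adjusted over the list alone (adjusted p = 2.22e-06; adjusted p = 0.281 with an estimated correlation). For heat shock the median was 1.51, and 2 of 6 passed adjusted over the list alone (adjusted p = 0.0008; adjusted p = 0.444 with an estimated correlation). Plastid ribosome and polymerase genes had a median of -1.65 (adjusted p = 4.01e-06; adjusted p = 0.444 with an estimated correlation). The test found 73 probe sets with a more positive TiO2 effect and 57 with a more negative one, against 94 and 44 with median-centred arrays. The count of 130 fell to 51 without KCl replicate 3, to 50 and 33 without TiO2 replicates 1 and 3, to 67, 61 and 28 without water replicates 1, 2 and 3, to 59 without CeO2 replicate 2, and to 5 without the 6 narrow arrays. Replicate numbers went together in KCl and water roots, and with the replicate number as a block 49 passed, and 7 of the 14 named genes that passed lost their call.

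In leaves the particle effects differed in 4 probe sets, 3 upward and 1 downward. AT3G10720 had a TiO2 effect larger by 5.05 ± 0.60 (adjusted p = 0.044) and AT5G11930 one smaller, at -4.53 ± 0.47 (adjusted p = 0.044). Each of these genes also passed between the KCl and water leaves, as given below, and that gap enters the difference. AT1G29670 at 4.63, AT5G22580 at 4.296, AT4G26950 at -3.43 and ATG8G at -2.44 did not pass. Adjusted over the list alone, 4 of 5 photosystem and Calvin cycle genes had a more positive TiO2 effect, with SBPASE at 2.66 and PRK at 2.19 (list adjusted p = 5.47e-05; adjusted p = 0.454 with an estimated correlation). So did 6 of 7 tubulins, with a median of 2.15, while 6 of 10 genes of the ATG8 list had a more negative one, with a median of -1.46 (adjusted p = 3.06e-07 and 0.000201; adjusted p = 0.454 for both with an estimated correlation). The count became 11 without TiO2 replicate 1, 2 without CeO2 replicate 1 and 0 without any other single array of the 12, and with median-centred arrays it was 0 up and 1 down. After quantile normalization 0 passed, so that both named genes lost their call.

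Across all probe sets the TiO2 and CeO2 effects, which share no arrays, correlated at r = -0.29 in roots and -0.281 in leaves, and 24 and 33 of 100 splits of the arrays, the real one included, gave a correlation as far from 0. The counts that follow are set against those of independent probe sets, which these are not. In roots 2 probe sets rose with TiO2 and fell with CeO2, against 0.00404, among them AT1G30820. At an unadjusted p under 0.05, 198 root probe sets were higher with TiO2 and lower with CeO2, against 37.2, 185 went the other way, against 59.1, and 29 and 34 moved up or down with both, against 49.5 and 44.3. In leaves 62 and 26 went in opposite directions, against 25.3 and 14.3, and 3 and 17 in the same direction, against 17.1 and 21.1. Without water replicate 1 the leaf correlation was -0.017.

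**Figure D3:**
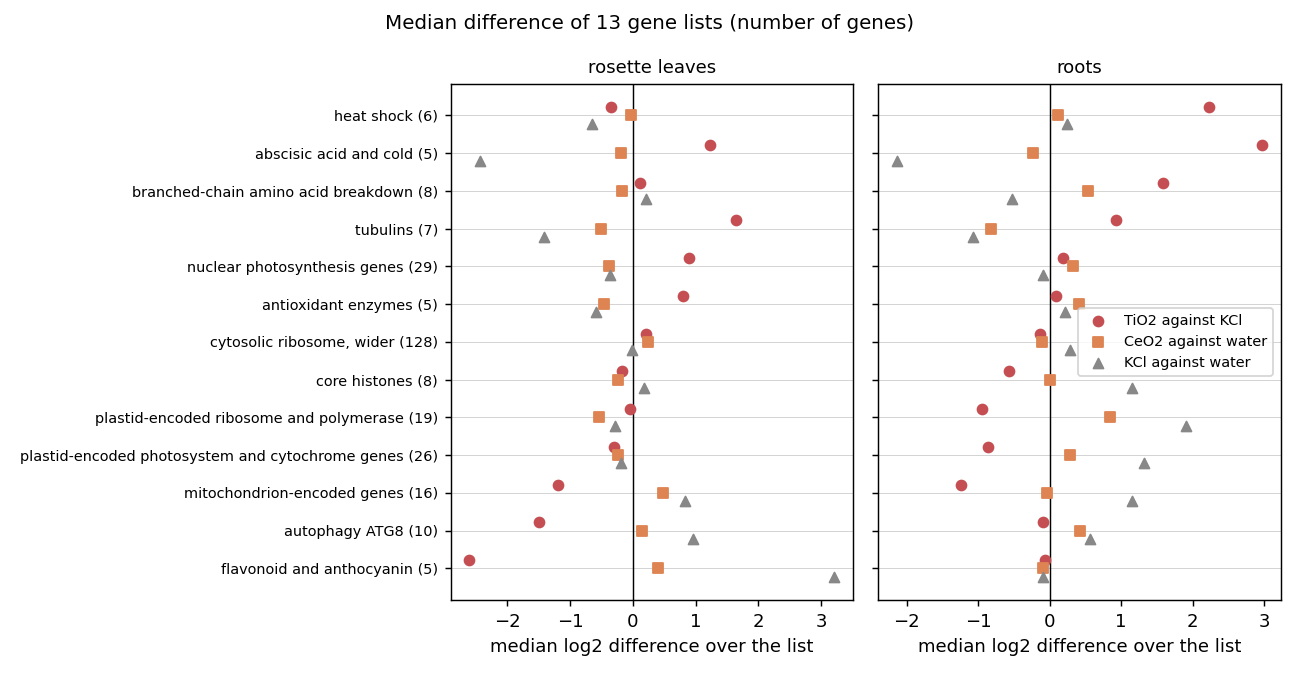
Median log2 difference of 13 gene lists in leaves and in roots for TiO2 against KCl, CeO2 against water and KCl against water, with the number of genes in brackets. The abscisic acid and cold list lies at 2.97 for TiO2 and -2.14 for KCl in roots; the KCl arrays enter both of these comparisons.

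The controls, KCl and water, also differed, and the KCl arrays enter both this comparison and that of TiO2. In roots the core histone genes lay higher with KCl, with a median of 1.16, and 4 of 8 rose adjusted over the list alone, such as AT2G37470 at 2.16, HTB1 at 1.79 and AT2G28720 at 1.71 (adjusted p = 1.18e-06; adjusted p = 0.0262 with an estimated correlation). All 19 plastid-encoded ribosome and polymerase genes were higher, and 11 rose adjusted over the list alone, with rpl32 at 3.08 and rpl20 at 2.77 (median 1.91, adjusted p = 3.16e-11; adjusted p = 0.359 with an estimated correlation). Among 26 plastid-encoded photosystem and cytochrome genes 6 rose adjusted over the list alone, such as psaI at 3.46 (median 1.32, adjusted p = 4.18e-07; adjusted p = 0.472 with an estimated correlation). The mitochondrial genes nad9 and nad4 rose adjusted over the list alone at 2.02 and 1.72 (list median 1.15, adjusted p = 4.76e-05; adjusted p = 0.472 with an estimated correlation). LTI30 and COR47 of the abscisic acid and cold list fell adjusted over the list alone at -2.88 and -2.26 (median -2.14, adjusted p = 0.000697; adjusted p = 0.359 with an estimated correlation). KCl roots 1 and 3 and water root 1 were among the narrow arrays. Over all probe sets AT1G31050 at 3.20 ± 0.45, AT1G72920 at 2.79, AT1G23410 at 2.74, LHW at 2.55 and AT5G48460 at 2.01 rose. AT4G34950 at -3.00, AT1G30820 at -2.60, AT1G16840 at -2.38, AT5G18490 at -2.28 and GSA1 at -1.36 ± 0.16 (adjusted p = 0.0344) fell. In all 11 rose and 16 fell, against 25 and 12 when quantile-normalized again and 7 and 21 with median-centred arrays. With the replicate number as a block or in a fit to the compared groups alone 0 passed. The count was 12, 17 and 1 without KCl replicates 1, 2 and 3, and 0 without any water array or without the narrow arrays, with 2636 at an unadjusted p under 0.05.

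In leaves all 5 flavonoid genes rose with KCl over water adjusted over the list alone, with DFR (dihydroflavonol reductase) at 4.74 and UF3GT at 3.47 (median 3.21, adjusted p = 1.09e-05; adjusted p = 0.359 with an estimated correlation). DFR averaged 8.73 ± 2.14 in KCl leaves, 5.84 ± 2.70 in TiO2 leaves, 3.99 ± 0.75 in water leaves and 4.26 ± 1.102 in CeO2 leaves. In the ATG8 list 6 of 10 rose adjusted over the list alone, ATG8G at 1.78 among them (median 0.95, adjusted p = 0.000194; adjusted p = 0.527 with an estimated correlation). Of 7 tubulins 5 fell adjusted over the list alone, such as TUB7 at -2.15 (median -1.41, adjusted p = 7.24e-06; adjusted p = 0.359 with an estimated correlation). LTI30 fell at -3.52 adjusted over the list alone, and the 5 abscisic acid and cold genes had a median of -2.43 (adjusted p = 0.00115; adjusted p = 0.359 with an estimated correlation). The sugar transporter SWEET13 rose adjusted over its list alone, at 3.04. The nitrate transporter NRT2.5, the only named gene of its list, rose at 2.16 at an unadjusted p under 0.05. Over all probe sets AT5G11930 at 3.32 ± 0.33 (adjusted p = 0.00849), AT4G26950 at 3.08 and AT2G36970 at 2.42 rose. AT3G10720 at -4.53 ± 0.42 (adjusted p = 0.00642), AT5G22580 at -3.91, AT2G16660 at -3.62, AT1G29670 at -3.26 and AT2G43590, of the chitinase family, at -2.91 fell. In all 9 rose and 34 fell, against 6 and 12 when quantile-normalized again. In a fit to the compared groups alone 8 passed, 2 of them among the 43, and all 8 passing genes named here lost their call. The count was 3 without KCl replicate 3, and 4, 11 and 88 without water replicates 1, 2 and 3. Without the narrow arrays, KCl leaf 2 among them, 111 passed.

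Group means of all probe sets were compared pair by pair. In roots the median absolute difference between groups was 0.187 for TiO2 and water, the smallest of the 6 pairs, 0.232 for TiO2 and CeO2, 0.237 for water and CeO2, and 0.28, 0.295 and 0.309 for KCl with water, TiO2 and CeO2. KCl roots, with 2 of their 3 arrays narrow (lower quartiles of 3.90 and 3.74), also had the highest spread within a group, a median SD of 0.401. In leaves the median absolute difference was 0.17 for water and CeO2, 0.203 for KCl and CeO2, 0.214 for TiO2 and water, 0.238 for KCl and water, 0.272 for TiO2 and CeO2 and 0.291 for KCl and TiO2.

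The TiO2 effect was also compared between roots and leaves. Heat shock genes had the more positive effect in roots, with 5 of 6 passing adjusted over the list alone and AT1G53540 at 4.56 (median 2.91, adjusted p = 8.99e-06; adjusted p = 0.341 with an estimated correlation). Among flavonoid genes 3 of 5 did, such as AT4G14090 at 2.75 (median 2.398, adjusted p = 0.000123; adjusted p = 0.341 with an estimated correlation). In leaves alone that list's median was -2.61 against KCl, and KCl leaves held the highest leaf mean of each of the 5 genes. AT4G14090 averaged 7.55 ± 1.965 in KCl leaves against 4.94 ± 0.81, 4.34 ± 0.28 and 4.50 ± 0.46 in TiO2, water and CeO2 leaves. Over all probe sets AT4G26950 had the more positive effect in roots, by 4.17 (adjusted p = 0.0332), and AT1G66020 the more negative, at -3.69 (adjusted p = 0.00639). In all 21 probe sets had a more positive effect in roots and 26 a more negative one, against 34 and 15 with median-centred arrays. The count of 47 became 23 and 9 without leaf KCl replicates 1 and 3, 148, 2 and 2 without leaf TiO2 replicates 1, 2 and 3, 22 and 24 without root KCl replicates 2 and 3, and 18, 201 and 3 without root TiO2 replicates 1, 2 and 3, and 152 without the narrow arrays. In a fit to the compared groups alone 24 passed, and 6 of the 10 passing genes named by the rule lost their call. The CeO2 effect differed between the tissues in 1 probe set, which has no named gene, and in 3 without root CeO2 replicate 2. The nuclear photosynthesis genes had a CeO2 effect more positive in roots, with a median of 0.77, and RCA passed adjusted over the list alone at 2.45 (list adjusted p = 8.66e-08; adjusted p = 0.418 with an estimated correlation).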

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

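All tests of splits of the arrays, the tests on the KCl controls, and the fits with the lower quartile as a covariate or without the narrow arrays were chosen only after the results had been seen.

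The effect of TiO2 differed between roots and leaves in 47 probe sets, by the test of the difference itself. Among 100 splits of the arrays within each pair of groups, 4 gave as many, the real one included. That share is under 0.05 but was not adjusted for the number of such tests, so it does not exclude chance. The highest of the other splits gave 307, several times the real count, which points to a structure of the samples; what it is was not tested. The named genes with the more positive effect in roots were AT4G26950 (4.17), AT2G34340 (3.83), AT2G39725 (3.73), AT2G43140 (3.63) and AT5G51680 (3.52). Those with the more negative effect in roots were ZW9 (-4.17), AT1G66020 (-3.69), AT1G29670 (-3.46), AT3G12710 (-3.41) and AT1G31050 (-3.35). For AT4G26950 and AT1G29670 the leaf part of the difference rests on KCl leaves that stand apart from the other 3 leaf groups (6.97 against 3.52 to 3.89, and 6.67 against 9.23 to 10.59). The effect of CeO2 differed between the tissues in 1 probe set, without a named gene. Chance cannot be excluded there: 19 of 100 splits gave as many, and the highest other gave 22. The splits did not keep replicate numbers together, although these went together in leaves and roots given CeO2.

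Among probe sets called for TiO2 the KCl mean lay farther than the TiO2 mean from the average of the water and CeO2 groups in 54 of 79 in roots and 5 of 5 in leaves. At an unadjusted p under 0.05 it did so in 74% in roots but 53.6% in leaves. Where water and CeO2 groups lie apart, as for AT1G30820 in roots, this does not tell which group moved. A lasting difference between the titania and the ceria experiment would move KCl minus water and TiO2 minus CeO2, which share no array, alike. They correlated across probe sets at 0.116 in leaves (-0.044 to 0.229 with each array left out) and -0.291 in roots (-0.366 to -0.189). No strong positive correlation was thus seen. How far it varies by chance was not counted. The correlation of the TiO2 and CeO2 effects reached 0.599 in leaves and 0.553 in roots, in absolute value, in other splits of the arrays. TiO2 minus CeO2 also holds both particle effects, so a lasting difference is not excluded. In roots 69 of the 79 probe sets were called again with the lower quartile in the fit. The mean lower quartile was 3.73 in KCl and 3.63 in TiO2 roots, so the covariate can move their difference only little. The narrow range of single arrays therefore stays open in roots. Leaving out the 6 narrow arrays moved the median absolute difference from 2.63 to 2.75, in a fit with 1 KCl array. In leaves the narrow range of single arrays stays open, since 1 of the 5 was called again with the lower quartile in the fit (median absolute difference 3.03 before and 2.83 after, standard error 0.331 and 0.346, adjusted p of those lost 0.0553 to 0.0942). The salt alone would not set KCl apart from TiO2, since the titania plants received it too; an unrecorded difference that touched the KCl plants alone was not tested.

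The heat shock genes were higher in TiO2 roots, with a median of 2.22. The KCl controls are argued against as the cause, since TiO2 roots lay 2.71 above the mean of the water and CeO2 roots at the median, with all 6 genes between 1.25 and 4.17. Handling that raises rapid stress genes as well is argued against by the 16 rapid stress and calcium-binding genes, with a median of 0.011 and an upper quartile of 0.95; handling that raises heat shock genes alone was not tested. A single TiO2 array cannot be told apart from the group's response, because the median was 2.53, 2.75 and 1.54 without TiO2 replicates 1, 2 and 3, and the last lies between the bounds set in advance. A response of the root to nano-titania may account for these genes, as a hypothesis found on the same arrays.

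Plastid-encoded ribosome and polymerase transcripts were higher in KCl than in water roots, with a median of 1.91. With the lower quartile of each array in the fit it was 2.09. The mean lower quartile was 3.73 in KCl and 3.65 in water roots, so the covariate can move this difference only little. The narrow range of single arrays therefore stays open as a cause. TiO2 roots lay between, at -0.94 from KCl, and CeO2 roots at 0.85 from water. The salt, which the titania plants also received, would not alone place TiO2 roots below KCl. An unrecorded difference that touched the KCl plants was not tested.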

How the results depend on the processing

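The fits with the lower quartile of an array as a covariate and without the narrow arrays were chosen only after the arrays had been seen; all others were fixed before.

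All 198 passing results of named genes kept their direction after quantile normalization, with median-centred arrays, with array weights and with the covariate; most other settings could not turn a direction, because they leave the difference itself unchanged or leave out arrays of groups that do not overlap. Of 2100 values with an array left out, 1708 still passed and 392 did not. Of the 198, 157 passed with the replicate block and 183 after quantile normalization. Roots against leaves in control plants supplied 126 of the 198 and 1512 of the 2100. It kept 1456 of the 1512, 126 with the block and 125 after quantile normalization. Each other comparison kept a smaller share with an array left out, such as 51 of 138 for TiO2 against KCl in roots. For KCl against water in leaves it was 23 of 48. With the block 5 of the 23 genes of TiO2 against KCl in roots passed. Of 104 list calls, 102 held with the block, 91 after quantile normalization and 64 without each array in turn; among 930 values with an array left out, 86 lost the call and 5 more turned in sign, uncalled. Counts of passing probe sets were less stable: of 234 alternatives, 101 lay within 1.5 times the reported count, 57 gave more and 76 fewer. Roots against leaves in control plants gave 7873 and stayed within 1.5 times of it in every alternative (6838 to 7894 with an array left out). Array weights moved some counts most, such as from 79 to 7292 for TiO2 in roots; the cause was not tested. The arrays' spread limits the calls. In simulated data with independent noise 53 of 200 changes of 1 and 124 of 200 changes of 2 were recovered in TiO2 roots.

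The reported count of passing probe sets is given with each alternative that moved it by more than 1.5 times. The threshold of 0.1 admits more by construction; for the other moves the cause was not tested.

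For TiO2 in leaves the count of 5 became 9 with the block, 28 with the compared groups, 47 with all 24 arrays, 11 above the median signal, 3 with median-centred arrays, 4511 with array weights, 81 at an adjusted p under 0.1, 1854 at an unadjusted p under 0.05 with a change of at least 1, 1 with the covariate and 8 without the narrow arrays, and ran from 0 to 135 with an array left out. For CeO2 in leaves the count of 0 became 1 with all 24 arrays and 146 at the unadjusted p with a change of at least 1, and was 0 with any array left out. For the difference between particles in leaves the 4 became 11 with all 24 arrays, 0 after quantile normalization, 1 with median-centred arrays, 1222 with weights, 1975 at the unadjusted p and 0 with the covariate, and ran from 0 to 11. For KCl against water in leaves the 43 became 122 with the block, 8 with the compared groups, 100 with all 24 arrays, 105 above the median signal, 18 after quantile normalization, 372 with weights, 185 at 0.1, 1516 at the unadjusted p, 158 with the covariate and 111 without the narrow arrays, and ran from 3 to 88.

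For TiO2 in roots the 79 became 34 with the block, 3 with the compared groups, 610 with all 24 arrays, 7292 with weights, 313 at 0.1, 1826 at the unadjusted p, 148 with the covariate and 0 without the narrow arrays, and ran from 4 to 456. For CeO2 in roots the 4 became 0 with the block, with the compared groups, above the median signal and without the narrow arrays, 65 with all 24 arrays, 2 above the 25th percentile and after quantile normalization, 1 with median-centred arrays and with the intensity trend, 4760 with weights, 8 at 0.1 and 911 at the unadjusted p, and ran from 0 to 4. For the difference between particles in roots the 130 became 49 with the block, 567 with all 24 arrays, 7279 with weights, 338 at 0.1, 2462 at the unadjusted p, 305 with the covariate and 5 without the narrow arrays, and ran from 28 to 187. For KCl against water in roots the 27 became 0 with the block, with the compared groups and without the narrow arrays, 459 with all 24 arrays, 16 above the median signal, 5416 with weights, 240 at 0.1, 1670 at the unadjusted p and 237 with the covariate, and ran from 0 to 17.

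For the TiO2 effect in roots against leaves the 47 became 31 with the block, 24 with the compared groups, 26 above the median signal, 4147 with weights, 168 at 0.1, 2132 at the unadjusted p, 147 with the covariate and 152 without the narrow arrays, and ran from 2 to 201. For the CeO2 effect in roots against leaves the 1 became 0 with the compared groups, above the median signal and without the narrow arrays, 841 with weights, 823 at the unadjusted p and 3 with the covariate, and ran from 1 to 3. The correlation of the TiO2 and CeO2 effects in roots, -0.29, was -0.163 by Spearman and ran from -0.348 to -0.161 with an array left out; in leaves, at -0.281, it ran from -0.487 to -0.017. A fit to all 24 arrays for comparisons between tissues is the reported one and gives no separate value.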

Other observations

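All tests of splits in this part were chosen only after the results had been seen.

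Further genes and lists changed in ways not described above. In TiO2 roots, adjusted over the list alone, the pyruvate decarboxylase PDC2 rose at 2.01, the copper chaperone CCS at 1.12 and the glycosyltransferase UGT87A2 at 2.83. The clock gene GI (GIGANTEA), the only named gene of its list, rose at 0.79 at an unadjusted p under 0.05. The 47 UDP-glycosyltransferases had a median of 0.12 with 3 rising adjusted over the list alone (adjusted p = 0.00349; adjusted p = 0.423 with an estimated correlation), a call that failed without KCl replicate 2 (adjusted p = 0.0694). In TiO2 leaves, adjusted over the list alone, the plant defensin PDF1.2 fell at -2.69, while the endoglucanase GH9B7 rose at 1.98 and GSTU20 at 1.09. The nitrate transporter NRT2.5, the only named gene of its list, fell at -1.85 at an unadjusted p under 0.05. The 128 cytosolic ribosomal genes had a median of 0.21 in TiO2 leaves (adjusted p = 0.000739; adjusted p = 0.792 with an estimated correlation), a call that failed without KCl replicate 1 (adjusted p = 0.418).

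Splits of the arrays into other groups of the same sizes were counted for the remaining comparisons. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In these the real split and the highest other gave 5 and 0 for TiO2 in leaves, 0 and 1 for CeO2 in leaves, 43 and 0 for KCl against water in leaves, 79 and 12 for TiO2 in roots, 4 and 2 for CeO2 in roots and 27 and 0 for KCl against water in roots. As many probe sets as the real split came from 1 of the 10 in each case, except CeO2 in leaves with 10 of the 10. For KCl against water in roots, where replicate numbers went together, the other splits that part all 3 pairs of numbers gave 0 as well. For the difference between particles, 4 of 100 leaf splits and 3 of 100 root splits gave as many as the real 4 and 130. These shares are under 0.05 but were not adjusted for the number of such tests, so they do not exclude chance. The highest others, 1660 and 1312, are many times the real counts and point to a structure of the samples that was not tested. These splits did not keep replicate numbers together, and with the replicate number as a block the root count was 49. For roots against leaves in control plants 1 of 100 splits gave as many as 7873, the real one itself, and the highest other gave 3350. That share was not adjusted for the number of tests either, so the splits alone do not exclude chance.

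The opposite directions of the TiO2 and CeO2 effects were tested in the same way. In leaves 33 of 100 splits gave a correlation as far from 0 as -0.281, with 0.599 as the highest other, and in roots 24 of 100 did for -0.29, with 0.553 as the highest other. Chance cannot be excluded for either. The splits did not keep replicate numbers together, although these went together in KCl and water roots.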
